A study of Mus musculus with 2 samples.

How the data were processed

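Brain natural killer (NK) cells had been sorted by fluorescence-activated cell sorting from 8-month-old female mice and made into single-cell libraries with the 10x Genomics Chromium chemistry that reads the 5′ end of transcripts, per the labels' protocols. There was 1 wildtype library (C57BL/6) and 1 library of 3xTg-AD mice, a transgenic model of Alzheimer's disease. The number of mice behind each library and the genetic background of the 3xTg-AD animals are not given in the sources used here. Reads were 75 bases long and paired, per the labels' protocols.

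The authors deposited a matrix of counts for each library, in which a value is the number of unique molecular identifiers (UMIs) of a gene in a barcode. Cell Ranger 3.1.0, STAR and the mm10 genome are named in the submitters' processing notes, while the matrix headers carry software version 3.0.2, per the file headers. The gene annotation release used for counting is not given in the sources used here. Each deposited matrix listed 31053 genes, and no normalization had been applied to the deposited counts. Gene coordinates come from GENCODE M21 on the same build, matched by Ensembl identifier, and all 117 named genes had one.

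Barcodes with fewer than 300 genes or more than 10% mitochondrial UMIs were left out, as were doublets called by Scrublet in each library alone. This left out 45 wildtype and 10 3xTg-AD barcodes for few genes, 2 and 0 for mitochondrial share, and 11 and 22 as doublets, so that 1651 and 1663 barcodes were kept. Both libraries were clustered together without integration (10000-count normalization, log transform, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0) in scanpy 1.11.5 under Python 3.11.15, with igraph 0.11.9. Cell type markers, gene lists, thresholds and the rule for named genes were fixed before the data were examined, and clusters were named from those markers. A cluster kept its name only if no other class had more markers among its top 10 genes by fold. 5 barcodes inside clusters 3 and 12 drew over 20% of their UMIs from the erythroid or neutrophil marker list and were taken out before clusters were named, a rule set after seeing the data. With them, the naming rule leaves clusters 3 and 12 unnamed, because they hold 3 and 0 NK markers among their top 10 genes against 4 erythroid and 4 neutrophil markers, so this removal is what made these clusters NK-like. Their shares ran from 41.5% to 83.5%, and the next highest barcodes held 0.186% and 0.142%.

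With 1 library per group there is no replicate, so no test was made and no p-value or standard error is given. Counts were summed over the NK-like cells of each library and scaled by that sum to CPM. Ratios are 3xTg-AD over wildtype, with exact conditional (binomial) 95% intervals for a ratio of Poisson counts. Shares have exact Clopper-Pearson intervals. All intervals cover counting error only, and neither animals nor preparations. Those of ratios and list medians also leave out variation between cells, so they can be too narrow where few cells hold a gene's UMIs. For example, the 108 wildtype UMIs of Ly6a lay in 1.53% of wildtype NK-like cells, and the 232 of Ifi27l2a in 1.95%. Genes needed 100 UMIs over both libraries, and list members needed 20. A gene at 0 in one library was set to a floor of 3 counts over the summed cells for a bound on its fold. A list was described by its members' median log2 ratio and by the percentile of that median among 10000 random lists matched on mean expression in 20 bins. To compare shares of cells, each NK-like cell was thinned to 1400 UMIs, which left out 127 wildtype and 89 3xTg-AD cells as shallower. Another class was compared only with at least 50 cells in each library.

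The genes named in the text follow a rule set with the design. It takes the 15 higher and 15 lower genes whose counting interval lay farthest from a ratio of 1, leaving out ribosomal protein and mitochondrial genes and receptor variable segments. It adds up to 4 members of each of 24 fixed lists with the largest absolute log2 ratio, and a fixed set of further genes whatever their values, among them NK genes, App and Mapt. Not every gene and list that the rule takes is printed. Hspa1a and Hspa1b, the Klra genes, and the histone genes have near-identical copies, so the split of counts between such copies is uncertain. Gm15987, Gm35082 and Gm42031 are predicted genes whose counts could include those of overlapping genes.

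The ratios, intervals, list percentiles and thinning were tested on simulated data made from the real means and totals of the NK-like comparison, with 200 of the genes changed by known folds. The simulated sums were Poisson counts, so their intervals were not checked against variation between cells. Of 7097 genes tested there, those simulated at 4-fold came out at a median of 3.88-fold, those at 2-fold at 1.97-fold and those at 1.5-fold at 1.41-fold. The intervals held the simulated fold for 95.8% of unchanged genes, 90% of genes at 1.5-fold, 96% at 2-fold, 92% at 4-fold and 93.0% of genes lowered to 0.25 of their level. Of 100 unchanged random lists, 4 lay outside the central 95%. Their genes were drawn at random from independent counts, so this does not check the percentiles of lists whose genes vary together.

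Alternatives covered scaling (edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios factors, and totals without ribosomal and mitochondrial genes), equal weight per cell, thinning, cell filters, doublets, resolution and count minimums. edgeR and DESeq2 served for scaling factors alone. 6 further alternatives were chosen after seeing the data: the naming rule alone with no barcode taken out (clusters 3 and 12 not NK-like), the 5 removed barcodes left in with these clusters as NK-like, cluster 4, cluster 11, or clusters 3 and 9 left out, and cluster 5 added.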

Results

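To compare NK cells sorted from brain between wildtype animals and the 3xTg-AD line, 1 library of each was read as UMI counts per barcode. The wildtype library held 1709 barcodes and 5559995 UMIs, with a median of 2930 UMIs and 1361 genes per barcode. The 3xTg-AD library held 1695 barcodes and 5468455 UMIs, with medians of 2846 UMIs and 1378 genes. Median mitochondrial shares were 1.45% and 1.24%, and median ribosomal protein shares were 17.3% and 15.5%, in wildtype and 3xTg-AD. Each group has 1 library, so the differences below describe these libraries and have no replicate check.

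Most sorted barcodes were NK-like, marked by Gzma and Prf1, which encode cytotoxic granule proteins. They made up 87.0% (95% interval 85.3 to 88.6) of 1651 kept wildtype barcodes and 89.3% (87.7 to 90.7) of 1663 3xTg-AD barcodes. Clusters 3 and 12 count as NK-like only because 5 barcodes with erythroid or neutrophil markers were taken out after seeing the data, and without that step NK-like shares were 76.7% and 82.1%. T-like barcodes, led by Cd3e, were 1.45% and 1.08%, microglia-like barcodes were 0.787% and 1.92%, and erythroid-like barcodes were 4 and 0. C1qa, a microglia marker, was found in 53.8% of the 13 wildtype and 93.8% of the 32 3xTg-AD microglia-like barcodes. Ttr, which is not on the microglia marker list, had the largest fold in this group over other classes. The wildtype ones may therefore include other cells. A further group, called cluster 5, had Gzmc, Inpp4b, Cxcr6 and Itga1 among its leading genes. It stayed unnamed because its top genes held 1 marker of type 1 innate lymphoid cells and 2 of NK cells. At Leiden resolution 2.0, a Gzmc-led cluster of 227 cells stayed unnamed. A cluster of 66 cells led by Tmem176b, with Cxcr6, was there named as type 1 innate lymphoid, by 4 markers against 2 of NK cells. Cluster 5 may thus hold more than 1 kind of cell. Cluster 5 held 10.5% of wildtype and 7.64% of 3xTg-AD barcodes. Clustered without the genes that differed at least 1.5-fold between the libraries, the group with most of these leading genes held 13.6% and 7.94%. It had 357 cells against 300 in cluster 5, with Ifi27l2a among its top genes over other classes. Cluster 11, led by interferon genes in the main clustering, had no counterpart there. That group may therefore hold cells of other clusters. The sort sets all of these shares.

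To ask how NK-like cells differed between the brains, counts were summed over 1437 wildtype and 1485 3xTg-AD cells (4433781 and 4481415 UMIs). Heat-shock genes, immediate early genes and histone genes led those higher in the 3xTg-AD library, and interferon-stimulated genes led those lower. Of 7116 genes with at least 100 UMIs, 46 were at least 2-fold higher and 53 at least 2-fold lower in the 3xTg-AD library, while 254 and 176 differed at least 1.5-fold in these directions. The median gene had a log2 ratio of 0.05. The shares of thinned cells with a UMI differed in the same direction for all 30 genes that the size rule named, which follows largely from how they were chosen. Clusters 0, 1, 3 and 4 held most of the wildtype NK-like cells and clusters 2, 4, 6 and 7 most of the 3xTg-AD ones, so the sums weight partly different clusters. Of 24 gene lists, 8 lay outside the central 95% of matched random lists.

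**Figure D1:**
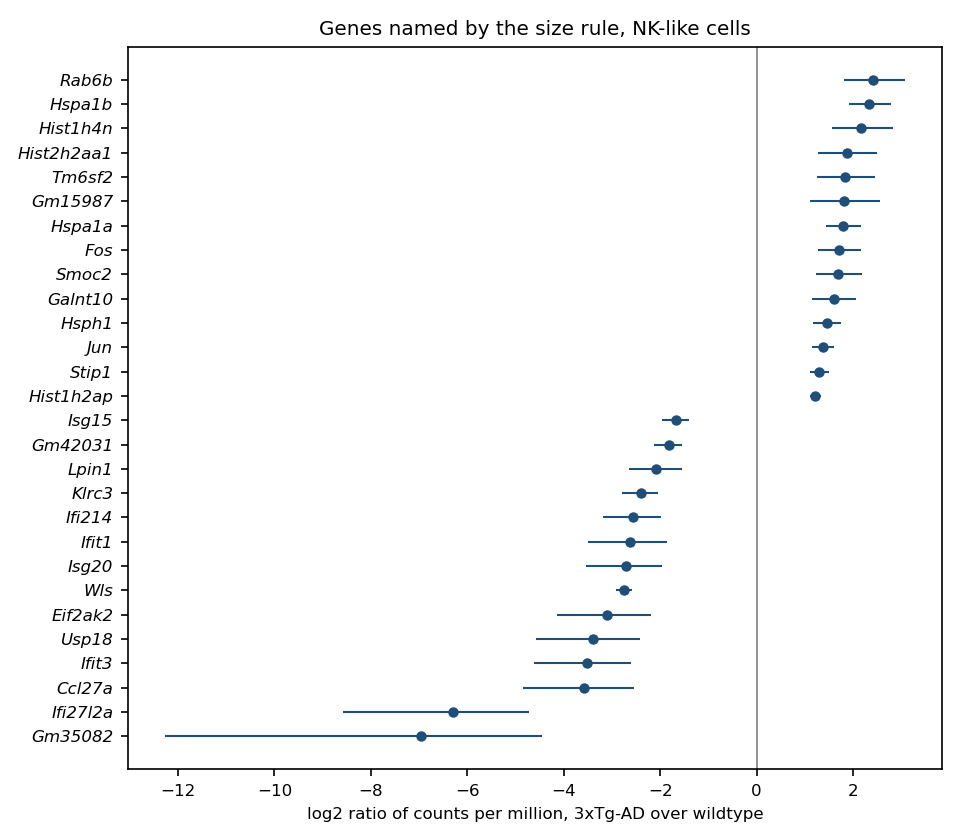
Log2 ratio of CPM, 3xTg-AD over wildtype, for most of the genes named by the size rule in NK-like cells (points), with 95% counting intervals (lines). Rab6b and Hspa1b lie at the top and Gm35082 and Ifi27l2a at the bottom, and Ly6a, with 108 UMIs in wildtype and 0 in 3xTg-AD, is not drawn.

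Heat-shock and immediate early genes were higher in 3xTg-AD NK-like cells. Hspa1b and Hspa1a, which encode inducible HSP70 chaperones, were 5.06-fold (3.76 to 6.93) and 3.49-fold (2.73 to 4.50) higher. Hsph1, an HSP110 chaperone, was 2.76-fold (2.26 to 3.38) higher, and Stip1, a co-chaperone linking HSP70 and HSP90, was 2.46-fold (2.15 to 2.81) higher. The AP-1 genes Fos and Jun were 3.28-fold (2.43 to 4.47) and 2.61-fold (2.23 to 3.06) higher. In the list of immediate early and dissociation stress genes, 17 of 42 measured members were at least 1.5-fold higher and 5 at least 1.5-fold lower, with a median log2 ratio of 0.40 (percentile 100). Handling during the sort can raise genes of this list, and it can differ between 2 preparations.

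Interferon-stimulated genes were lower in the 3xTg-AD library. Ifi27l2a had 232 UMIs in wildtype and 3 in 3xTg-AD NK-like cells, a ratio of 0.0128 (0.00262 to 0.0379). Ifit3 and Ifit1, which bind viral RNA or act with its sensors, were at ratios of 0.0868 (0.0405 to 0.166) and 0.162 (0.0888 to 0.276), and Isg15, a ubiquitin-like modifier, was at 0.314 (0.258 to 0.380). Usp18, a brake on interferon receptor signalling, was at 0.0947 (0.0420 to 0.188), and Eif2ak2, which encodes the RNA sensor PKR, at 0.117 (0.0565 to 0.219). Of 47 measured type I interferon response genes, 30 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median log2 ratio of -0.88 (percentile 0). The list of MHC class I and interferon gamma response genes had a median of -0.17 (percentile 0), with 8 of 37 at least 1.5-fold lower and 0 higher. Among them, Ly6a (Sca-1) had 108 UMIs in wildtype and 0 in 3xTg-AD, at least 36.4-fold lower against a floor of 3 counts (95% upper limit of the ratio 0.0344), and Socs1, an inhibitor of cytokine signalling, was at a ratio of 0.421 (0.365 to 0.486).

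Much of the interferon difference lay in few wildtype cells. With 10 or more UMIs of the type I interferon list after thinning, a limit chosen after seeing the data, there were 47 of 1310 wildtype cells (3.59%, 2.65 to 4.74) and 4 of 1396 3xTg-AD cells (0.287%, 0.0781 to 0.732). The score is a range, and 17 wildtype and 11 3xTg-AD cells lay between 8 and 12 UMIs. Without cluster 11, which holds 42 of the 47 wildtype cells, the median log2 ratio of the list was -0.29, with 15 of 40 members at least 1.5-fold lower and 4 higher, and that of the MHC class I and interferon gamma list was -0.08.

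**Figure D2:**
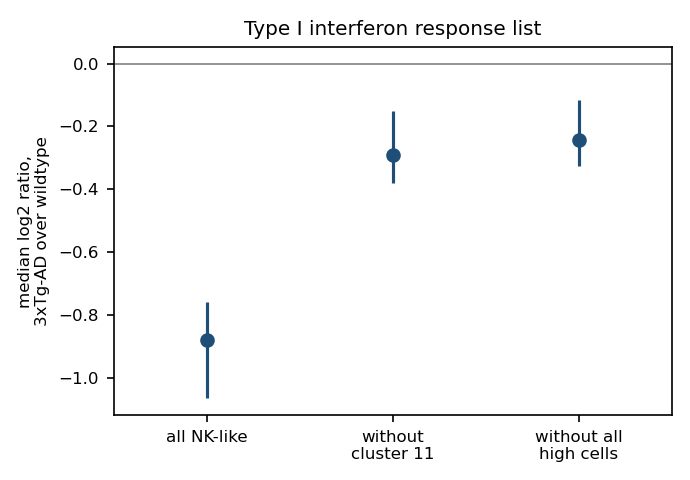
Median log2 ratio of the type I interferon response list, 3xTg-AD over wildtype, in all NK-like cells, without cluster 11, and without cluster 11 and any other cell whose share of these UMIs reached the limit. Lines are 95% intervals from 1000 Poisson resamples; the medians are -0.88, -0.29 and -0.24.

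NK receptor genes differed in both directions. The Ly49 genes encode NK receptors, many but not all of them for MHC class I. Among them, Klra8 was 1.93-fold (1.82 to 2.04) and Klra3 1.81-fold (1.64 to 1.99) higher in the 3xTg-AD library. Klra1 and Klra5 were at ratios of 0.357 (0.318 to 0.40) and 0.492 (0.380 to 0.633). The list had 3 of 9 measured members at least 1.5-fold higher and 2 lower, with a median of 0.35 (percentile 99.9). Klrc3, of the NKG2 family, was at a ratio of 0.189 (0.145 to 0.244), Klrc2 was 1.52-fold (1.41 to 1.65) higher, and Ncr1, which encodes the activating receptor NKp46, was 1.34-fold (1.30 to 1.38) higher. Inhibitory and checkpoint receptors had a median of 0.26 (percentile 99.9), with 2 of 16 at least 1.5-fold higher and 1 lower. They included Entpd1, the ectonucleotidase CD39, at 2.27-fold (1.90 to 2.73), Klri2 at 1.85-fold (1.70 to 2.01), and Tigit at a ratio of 0.529 (0.432 to 0.644). Without cluster 4 that median was 0.09 (percentile 78.7). Activating receptors and adaptors had a median of -0.01.

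Cytotoxic effector genes as a list lay close to 0. Their median log2 ratio was 0.00 over 18 measured members, with 0 at least 1.5-fold higher and 3 lower. Gzmb, a serine protease of cytotoxic granules, was at a ratio of 0.510 (0.495 to 0.524), whereas Gzma was at 0.979 (0.971 to 0.988) and Prf1, which encodes perforin, at 0.939 (0.905 to 0.973). The chemokine genes Ccl3 and Ccl4 were 1.41-fold (1.29 to 1.53) and 1.37-fold (1.32 to 1.43) higher, and Ccl5 was 1.11-fold (1.10 to 1.12) higher. Ifng was at 0.819 (0.663 to 1.01), a difference not detectable at this depth. The list of secreted cytokines and chemokines had a median of 0.14 (percentile 89.8).

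Maturation lists had medians near 0. Terminal maturation genes had a median of -0.03 and lay inside the central 95% of random lists under each alternative. Immature NK genes had -0.01, with 0 of 23 at least 1.5-fold higher and 6 lower, and tissue residency genes -0.06, but they lay below that range in 6 and 8 of 19 alternatives, with medians down to -0.18 and -0.23. Without cluster 11 the tissue residency median was 0.13. Within them, Il7r, the interleukin-7 receptor, was at a ratio of 0.365 (0.275 to 0.479), Ctla2a at 0.473 (0.418 to 0.536), Cx3cr1 at 0.678 (0.591 to 0.777) and S100a6 at 0.652 (0.627 to 0.679). Tbx21, which encodes the NK regulator T-bet, was 1.28-fold (1.19 to 1.38) higher, Eomes was at 1.09 (0.994 to 1.19) and Id2 was at 0.691 (0.646 to 0.738). NK transcription factors had a median of 0.06, trafficking receptors and integrins -0.03, and cytokine receptors 0.10. Ccr2, a receptor for the chemokine Ccl2, was at a ratio of 0.356 (0.297 to 0.423), and Il21r was 1.85-fold (1.51 to 2.27) higher.

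The G2 and M phase list depended on thinning and on which clusters counted as NK-like. G2 and M phase genes had a median of 0.27 (percentile 99.99), with 11 of 46 at least 1.5-fold higher and 4 lower, but -0.05 over thinned cells, where 23 members were measured, and 0.04 (percentile 43.8) with clusters 3 and 12 left out by the naming rule alone. S phase genes had a median of 0.16 (percentile 95.4), and Mki67 was at 1.27 (0.941 to 1.72). Thinned cells with 2 or more UMIs of the S phase list made up 36.5% (33.9 to 39.2) of wildtype and 38.8% (36.3 to 41.4) of 3xTg-AD cells, and of the G2 and M phase list 48.7% (46.0 to 51.4) and 49.8% (47.1 to 52.4). These shares also count genes that resting cells express, so they do not count dividing cells. The histone genes that the size rule named were higher, with Hist1h4n at 4.51-fold (2.95 to 7.11), Hist2h2aa1 at 3.66-fold (2.43 to 5.68) and Hist1h2ap at 2.32-fold (2.16 to 2.51). Not all histone genes were higher, and Hist1h4i was at a ratio of 0.729 (0.543 to 0.975).

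Genes of the protein synthesis and energy machinery differed little. Cytosolic ribosomal protein genes had a median of -0.17 (percentile 0) with 0 of 79 members past 1.5-fold, and nuclear-encoded oxidative phosphorylation genes, assembly factors included, had -0.05 (percentile 0.3). Mitochondrially encoded genes had -0.11, glycolysis genes 0.13, NF-kB and TNF signalling genes 0.15, and apoptosis and survival genes 0.07. Pim2, a survival kinase, was at a ratio of 0.397 (0.324 to 0.484).

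Several genes outside these groups were among the most different. Wls, the carrier for secretion of Wnt proteins, was at a ratio of 0.149 (0.132 to 0.168), from 481 CPM in wildtype to 71.6 CPM in 3xTg-AD (chromosome 3, 159839672 to 159938664, mm10). After thinning it was found in 44.4% (41.6 to 47.1) and 9.46% (7.97 to 11.1) of NK-like cells, and unthinned in 64.0% and 19.1%, at median depths of 2838 and 2763 UMIs. Of the microglia-like barcodes, 46.2% (19.2 to 74.9) of 13 in wildtype and 28.1% (13.7 to 46.7) of 32 in 3xTg-AD held a Wls UMI, and 23.1% and 53.1% held a UMI of Ncr1, an NK gene that they should lack, at median depths of 2475 and 3499.5 UMIs. C1qa was found in 53.8% of these wildtype and 93.8% of these 3xTg-AD barcodes, so not all need be microglia. Whether the Wls UMIs in 3xTg-AD NK-like cells are their own or free RNA is not settled by these few barcodes. Rab6b, a small GTPase of vesicle transport, was 5.33-fold (3.49 to 8.44) higher. Smoc2, Tm6sf2, Galnt10 and Gm15987 were between 3.02-fold and 3.57-fold higher. Gm35082, Ccl27a, Lpin1 and Gm42031 were at ratios of 0.0080, 0.083, 0.24 and 0.28.

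The list of loci that differ between C57BL/6 and other laboratory strains had a median of -0.03, with 3 of 20 measured members at least 1.5-fold higher and 7 lower. Over all 7116 genes with at least 100 UMIs, a higher minimum, these counts were 254 and 176. A strain difference can go in either direction, so a median near 0 does not show that these loci are alike. Ly6a, named above with the interferon genes, is on this list too, as are Klra1, Klra5, Klra8 and Klra3. App had 6 UMIs in wildtype and 7 in 3xTg-AD, and Mapt had 0 and 0. These are counts of the mouse genes and do not check the genotype, since the transgenes are human sequences.

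**Figure D3:**
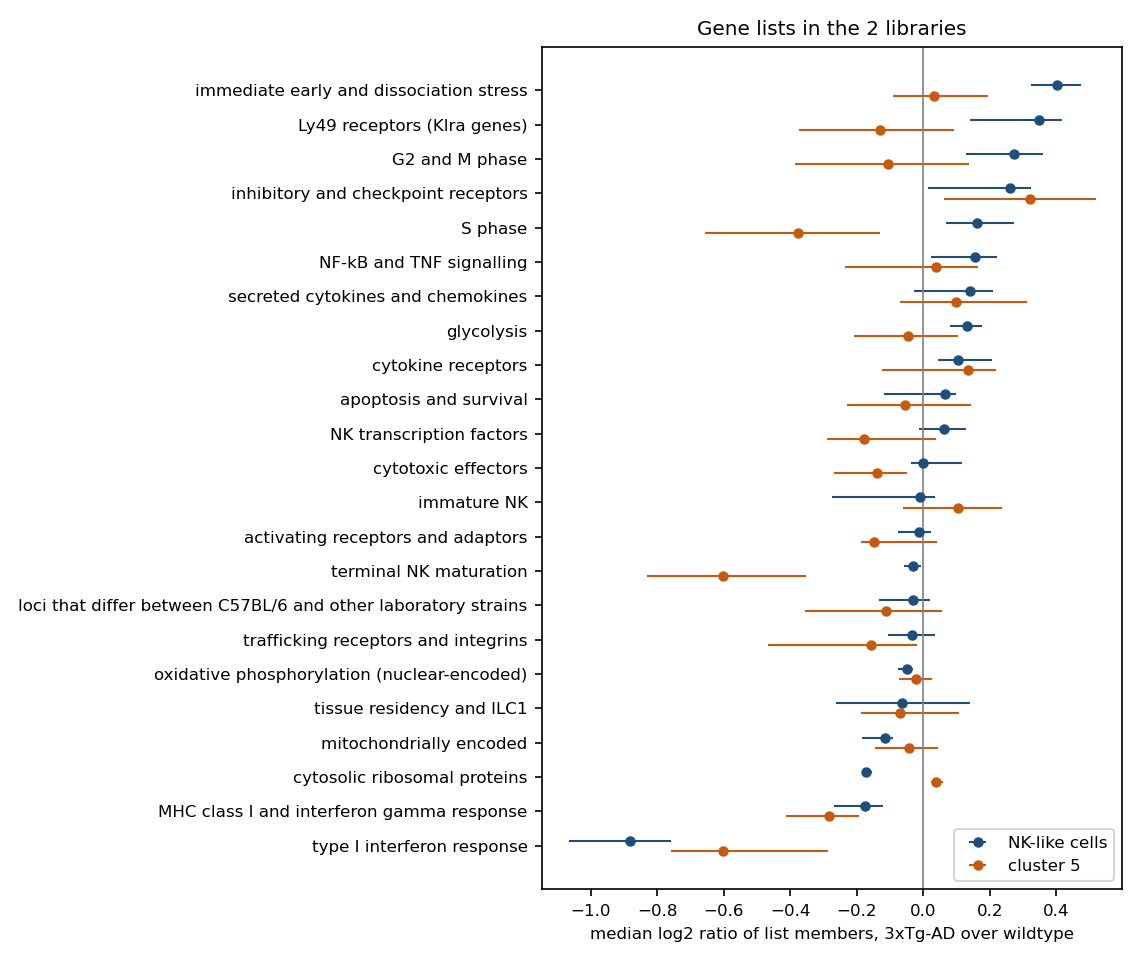
Median log2 ratio, 3xTg-AD over wildtype, of gene lists in NK-like cells (blue) and in cluster 5 (orange), with 95% intervals from 1000 Poisson resamples. The stress list lies at 0.40 in NK-like cells and 0.03 in cluster 5, and the type I interferon list at -0.88 and -0.60.

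To see whether another lymphocyte group of the same libraries differed likewise, the 173 wildtype and 127 3xTg-AD cells of cluster 5 were compared (1973 genes with at least 100 UMIs). Ncr1 was found in 89.0% and 96.9% of them, so the group is close to NK cells. Its leading gene Gzmc was itself at a ratio of 0.219 (0.182 to 0.262). Whether the make-up of the group differed between the libraries was not tested. Interferon genes were lower there too, with a median of -0.60 and 16 of 30 measured members at least 1.5-fold lower. Wls was at a ratio of 0.216 (0.150 to 0.303), Klra1 at 0.305 (0.189 to 0.476), and Ly6a had 58 UMIs in wildtype and 0 in 3xTg-AD, at least 15.2-fold lower against the same floor (95% upper limit of the ratio 0.0834). Klri2 was 2.19-fold (1.72 to 2.80) higher. The stress list had a median of 0.03 and Jun was at a ratio of 0.445 (0.276 to 0.698), while Hsph1 was 3.58-fold (1.75 to 7.89), Stip1 1.52-fold (1.01 to 2.32) and Hist1h2ap 3.32-fold (1.98 to 5.79) higher, and the differences from NK-like cells were not tested. Terminal maturation genes had a median of -0.60, with 11 of 20 at least 1.5-fold lower, and Gzma and Gzmb were at ratios of 0.398 (0.370 to 0.427) and 0.440 (0.407 to 0.475). In 3xTg-AD, Gzma in cluster 5 was at 0.0741 of its NK-like level. The UMIs of S1pr5, an NK gene, allow free RNA there up to 0.0740, so that Gzma could be free RNA. In wildtype these values were 0.182 and 0.0357. In all, 4 genes were at least 2-fold higher and 13 at least 2-fold lower.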

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

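The test of the interferon list without cluster 11 was chosen after its result was seen, and the other tests below were fixed before theirs, that within clusters made with all genes once the value within the other clusters was known, and that of free RNA once the cluster 5 median and the S1pr5 level were known.

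Jun differed in direction between the cell groups: its log2 ratio, 3xTg-AD over wildtype, was 1.38 in NK-like cells and -1.17 (-1.86 to -0.52) in cluster 5, a difference that was not tested. Microglia-like barcodes, which the sort should exclude, made up 1.92% of the 3xTg-AD barcodes against 0.787% of the wildtype ones. C1qa was found in 93.8% and 53.8% of them, so the wildtype group may hold other cells. A single neutrophil-like barcode, 0.0601% of the 3xTg-AD barcodes, had no counterpart in wildtype.

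Heat-shock and immediate early genes were higher in 3xTg-AD NK-like cells. Without the 5% of cells with the largest stress share in each library, the median log2 ratio of the 17 members at least 1.5-fold higher was 1.005 (0.89 to 1.17) against 1.03 with them, which argues against a few extreme cells. In cluster 5, 10 of these members were measured, with a median of 0.246 (0.02 to 0.39) against 0.94 for the same 10 genes in NK-like cells. A difference between the 2 preparations that reached every cell type was to give a cluster 5 median larger than this whole interval. To argue against it, the median was to lie under a second, lower limit. The median lies just above that lower limit with 0.94 as the reference, the one used, and would lie just below it with 1.03. The explanation therefore cannot be told apart on this value. A handling difference acting more on NK cells, and the genotype, both stay open, since each group is 1 preparation.

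Outside the stress list, the genes at least 2-fold different in NK-like cells may reflect inherited differences between the mouse lines as well as the transgenes. In cluster 5 their median log2 ratio, signed by the NK-like direction, was 0.607 (0.46 to 0.85), with 45 of 54 measured genes in the same direction, and 0.53 without the interferon lists. Any difference across a whole library would give this too, while free RNA from NK-like cells is argued against as the whole of it: with the most that the UMIs of S1pr5, an NK gene, allow in cluster 5 taken out (0.0357 and 0.0740 of NK-like levels in wildtype and 3xTg-AD), the median was 0.507 (0.43 to 0.83). Linked blocks could not be settled. Of genes of different families, 11 pairs lay within 1 megabase, against a median of 7 and a 95th percentile of 13 in random sets. Without the interferon lists there were 10, against 5 and 10, reached by 5.05% of random sets. On chromosome 8, Tm6sf2, Armc6, Arrdc2 and Ocel1 (starts 70072924 to 71371298) were all higher, and Mri1, Gadd45gip1 and Gm42031 (84249906 to 85125872) all lower. The paired genes on chromosomes 6 and 19 went in opposite directions, and both on chromosome 12 were lower. Whether neighbours share a direction more often than random sets was not tested. A different mixture of the states that clusters made with all genes mark is argued against only in part. Within the 7 clusters holding at least 50 cells of each library, the median was 1.195 and the lowest 1.05, so mixture is not the whole of it there. These medians cover 19 to 61 genes per cluster, and single genes can still follow the mixture. Clusters 0 (265 wildtype and 26 3xTg-AD cells), 9, 11 (53 and 3) and 12 held too few cells, so the states they mark were not covered. Clusters made without the differing genes (1.32) cannot part states that those genes mark, and finer states stay open.

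A small group of wildtype NK-like cells held strong interferon response genes. Cells of the 3xTg-AD line are argued against by Wls, a gene low in the 3xTg-AD library, which was at 0.764 (0.572 to 1.001) of its level in other wildtype NK-like cells. An animal of a further line without low Wls could give the same value, so that was not tested. Doublets or another cell type cannot be told apart: median UMIs were 0.977 times those of the others, but Ncr1 was found in 67.9% of these cells against 95.6%, with 0 UMIs of Lyz2 and Cd79a and 1 of C1qa, while the group held 25 of the 44 Plac8 UMIs and 38 of the 85 Cd74 UMIs of wildtype NK-like cells, besides 59 of 63 of Ifitm3 and 173 of 380 of Bst2, which interferon also induces. Part of the interferon difference remained outside this group. The list median was -0.291 (-0.38 to -0.15) without it, over 40 members against 47 with it, and -0.244 without every cell high in these genes. Taking cells out does not take out free RNA that they may have shed into other wildtype barcodes, which was not tested. The limit for this test was also set after its result, so whether the group is the source of the whole difference is not settled. Whether 1 animal carried these cells was not tested, as cells are not assigned to animals.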

How the results depend on the processing

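Alternatives that left out cluster 4, cluster 11 or clusters 3 and 9, added cluster 5, kept the erythroid and neutrophil barcodes, or used the naming rule with no barcode taken out were chosen after seeing the data. Across all alternatives, 419 list medians stayed within their counting interval, 34 moved and 3 reversed, and of the ratios of named genes 2050 stayed, 109 moved and 7 reversed. The 3 reversed medians are of lists whose interval in the report left out 0. Lists whose interval included 0 are not counted as reversed. Among these, immature NK genes, trafficking receptors and strain loci also changed sign, with medians up to 0.046, 0.039 and 0.037. The number of lists outside the central 95% of random lists stayed within 1.5 times its value of 8. Of lists inside it in the report, tissue residency and mitochondrially encoded genes lay outside in 8 of 19 alternatives each, immature NK genes in 6, trafficking receptors in 3, and S phase, activating receptor, cytokine receptor and apoptosis genes in 1 each, while the G2 and M phase list lay inside in 2 and the inhibitory receptor list in 1. The counts of genes at least 2-fold higher and lower were 27 and 27 over thinned cells (4823 genes tested), 82 and 95 with a minimum of 50 UMIs (8479 genes), and 17 and 19 with a minimum of 300 UMIs (4000 genes), where the number of genes tested differs by construction. Over all deposited barcodes 85 were higher, and the log2 ratio reversed for Cd74 (2.35), Cx3cr1 (0.11), Gzma (0.0012) and the terminal maturation list (0.026); that list was at 0.0019 in cells with Ncr1 or Klrb1c and no other-type marker, and Gzma at 0.0025 with equal weight per cell; the cause was not tested. Thinning reversed the G2 and M phase list (-0.054) and Cdk1 (-0.35), with fewer list members measured. With no barcode taken out, the naming rule leaves clusters 3 and 12 out of the NK-like cells by construction. NK-like barcodes were then 76.7% and 82.1%, and erythroid-like ones in wildtype and neutrophil-like ones in 3xTg-AD were 0. In that setting 47 genes were at least 2-fold higher and 53 lower, and Nusap1 (-1.62) and Ccnb2 (-0.035) reversed. Nusap1 is among the genes that lead cluster 12, so leaving that cluster out takes away part of its counts. Why Ccnb2 reversed was not tested. Clustered without the genes 1.5-fold different, NK-like barcodes were 84.6% of wildtype and the group matching cluster 5 was 13.6%. No cluster led by interferon genes was then left. That group had Ifi27l2a among its top genes, so it may have taken in such cells. Which cells moved was not tested. NK-like cells over the UMI limit of the S phase list were 66.7% and 71.2% without thinning and 4.73% and 6.52% at 4 or more UMIs, in wildtype and 3xTg-AD, and of the G2 and M phase list 79.8% and 78.5%, and 10.99% and 11.2%, shares that follow depth and limit by construction. No paired analysis was possible because each group has 1 library. Depth limits genes under 100 UMIs, which were not counted by fold; the few named singly have wide intervals or are given as counts.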

Other observations

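The lists and genes in this part, and the tests of cytokine signalling and ribosome biogenesis, were chosen after the data were seen; the test of histones without the cycling cluster was fixed before its result. A wider heat-shock response list had 14 of 19 measured members at least 1.5-fold higher in 3xTg-AD NK-like cells and 0 lower, with a median log2 ratio of 0.79. Bag3, a co-chaperone, was 2.39-fold (1.96 to 2.92) higher, and Hspa8 and Dnaja1, constitutive chaperone genes, were 2.04-fold (1.98 to 2.10) and 2.09-fold (1.98 to 2.22) higher. Genes of the unfolded protein response of the endoplasmic reticulum had a median of 0.11 (percentile 84.2), with 1 of 18 members at least 1.5-fold higher. In cluster 5 the heat-shock list had a median of 0.25 (percentile 99.9), with 4 of 18 members at least 1.5-fold higher and 1 lower, and the interval lay above 0 for 7 members, among them Hspa8 and Dnaja1, and below 0 for 0.

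In a list of STAT5-induced genes, 8 of 15 measured members were at least 1.5-fold lower in 3xTg-AD NK-like cells and 0 higher, with a median log2 ratio of -0.67, but 13 of its 18 genes had been seen before the list was written. Socs1, Cish, Myc, Pim2 and Gadd45g were at ratios of 0.42, 0.50, 0.49, 0.40 and 0.42, whereas Ccnd3 was 1.204-fold (1.15 to 1.26) higher and Ccnd2, Bcl2l1 and Socs3 had intervals that include 1. Gzmb, Gadd45g and Socs1 of this list were among the leading genes of cluster 1, which held 197 wildtype and 62 3xTg-AD cells. Leaving that cluster out shrinks the difference in part by construction, and the median was then -0.38. In cluster 5 the median of the list was 0.06 (percentile 76.2). Over the 2 measured members not seen before the list was written, the median lay at percentile 87.79. Weaker cytokine signalling thus stays a candidate explanation that too few genes could test. Ribosome biogenesis genes had a median of -0.25. Over the 36 members not seen before, it was -0.23 (percentile 0). Pno1, Mrto4 and Fbl of this list were also among the leading genes of cluster 1. Without that cluster the median of the whole list was -0.04 (percentile 2.63), and in cluster 5 it lay at percentile 26.4.

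Replication-dependent histone genes had a median log2 ratio of 0.72, with 26 of 45 measured members at least 1.5-fold higher and 0 lower. A candidate explanation, more cells in S phase, cannot be told apart: without cluster 12, which is led by cell cycle genes, the median over the 34 members still measured was 0.536 (0.38 to 0.75), with 16 at least 1.5-fold higher and 2 lower, against 0.66 for the same members with it, and the interval spans the limit set for the test. Histone copies are near-identical, and many of these transcripts lack a poly(A) tail, so a difference in capture stays open.

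T-like barcodes, 24 in wildtype and 18 in 3xTg-AD, carried genes of both gamma delta and alpha beta receptors. Trdc was found in 10 and 6 of them, Tcrg-V1 in 9 and 9, and Trav15-1-dv6-1 in 5 and 6, while Trbc2 was found in 10 and 12, Trbc1 in 4 and 7, Trac in 4 and 5, and Cd4 in 0 and 0. Among wildtype barcodes under 300 genes, 29 of 45 drew over 50% of their UMIs from erythroid genes, against 0 of 10 in 3xTg-AD. Hbb-bs was found in 2.37% of wildtype NK-like cells and in 0% of the 3xTg-AD ones. In the NK-like sums, monocyte or macrophage markers had 671 UMIs in wildtype and 260 in 3xTg-AD, of which Ccr2 had 487 and 175 and the interferon-stimulated gene Ifitm3 63 and 1. Dendritic cell markers had 698 and 383, of which Bst2, also interferon-stimulated, had 380 and 206 and Itgax 190 and 102.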
